A study of Homo sapiens with 12 samples.

How the data were processed

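Lamina contact was measured by DamID-seq, in which a bacterial adenine methylase (Dam) fused to lamin B1 marks DNA near the nuclear lamina and Dam alone marks accessible DNA. The cells were Tig3, a diploid human lung fibroblast line carrying the ecotropic receptor and hTERT. The 12 libraries hold 3 states, cycling, oncogene-induced senescence after BRAF (OIS) and quiescence after serum starvation, each with 2 Dam-LaminB1 and 2 Dam-only libraries at day 10 per the labels. Per the labels' protocols, cells grown in 9% serum received the Dam lentivirus on day 8 and were given 0.5 μM of a ligand called Sh for 24 h, and the starvation medium held 0% serum. States were taken from the sample titles and the cell stage label. The treatment text of the OIS samples describes the empty vector, which conflicts with their titles and cell stage, so the identity of those cells rests on the titles and the cell stage.

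Per the submitters' processing notes, bcl2fastq 1.8.4, cutadapt and Bowtie2 were used with genome build hg19. The versions of cutadapt and Bowtie2 and the roles of the tools are not given in the sources used here. The authors deposited, for each library and each bin of 100 kb, a linear ratio of observed to expected reads (OE ratio), and how the expected number was made is not given in the sources used here. Library means of these ratios lay between 0.990 and 1.03, so every value is relative to the rest of its own library and the total amount of lamina contact is not measured. Values stop at a maximum set per chromosome, between 1.12 and 2.56, and 1838 tested bins (6.57%) lie at that maximum in at least 1 library.

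A further file deposited by the authors gives, per the file headers, a log2 value per state and bin of 50 kb in hg19, a call of each bin inside or outside lamina-associated domains per state, and a class for Tig3 cells made with 3 other cell types. In that file the authors combined the replicates of a state, and the calling method is not given in the sources used here. Across 27875 bins the deposited log2 values correlated with the ratio computed here at r = 0.993 in cycling, 0.989 in OIS and 0.995 in quiescent cells, against 0.609, 0.507 and 0.744 for Dam-LaminB1 alone. The classes inside domains in Tig3 are constitutive domains (cLAD, inside in all other cell types) and facultative domains (fLAD, outside in at least 1 other type). Those outside in Tig3 are constitutive inter-domains (ciLAD, outside in all) and facultative inter-domains (fiLAD, inside in at least 1 other type). All 56669 bins with calls follow this rule. The calls given for HT1080 and KBM7 cells are equal in all 56669 bins and those for HT1080 and ES cells in 49234 (86.9%), so the classes rest on fewer distinct sets of calls than cell types named. That file has 1 broken line and was not used on chromosome 11 from 42400001 to 51650000 (9.25 Mb). Another 4 columns of per-sample values belong to other cell types and were not used.

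Low OE ratios within a bin are whole multiples of what 1 read is worth. Whole reads were recovered on this basis in 28286 of 28573 bins (99.0%) with a tolerance of 0.01 read. The recovered depth ran from 2366288 to 3221243 reads per library, with a median of 82 to 111 reads per bin. The median counting error of a log2 ratio was 0.21, against a replicate SD per bin of 0.23 in cycling, 0.25 in OIS and 0.25 in quiescent cells, so counting error makes up much of the spread of single bins. Counting errors treat reads as independent molecules. Replicate libraries differed by more than sampling noise, with a chi-square per degree of freedom between 1.22 and 1.87 for Dam-LaminB1 and between 1.11 and 1.22 for Dam-only, so none were counted as one library.

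For each replicate the value analysed was log2((Dam-LaminB1 + 0.05) / (Dam-only + 0.05)) of the OE ratios with the same title number, called the log2 ratio, and fold changes are on this scale with its pseudocount. Of 30376 bins, 1803 without a number and 612 at 0 in a library were left out, and 27961 bins (2796.1 Mb) on 22 autosomes and chromosome X were tested. A bin of 100 kb received a class where both of its 50 kb bins had the same one. The 3 states were compared in 1 limma fit of state means (lmFit, contrasts, eBayes with a trend), with 3 residual and 12.6 prior degrees of freedom, two-sided, with Benjamini-Hochberg adjustment over bins at 0.05. Rose, fell, higher and lower are used of bins and chromosomes that passed this test. The same test was run on the Dam-only libraries and on chromosome means, with adjustment over 23 chromosomes. The 12.6 prior degrees of freedom are those of the bin fit. On chromosome means, limma took the SE almost wholly from the spread pooled over chromosomes. Chromosomes of the same profiles are not independent replicates, so the p-values of chromosome means are too small. Changes of classes and of domain coverage are described without a p-value, since bins are not replicates. The contrast of chromosome ends (within 2 Mb of an outer end) with the rest was tested with an exact permutation of the replicates, for which 2 against 2 cannot give a two-sided p under 0.3333, and with 1000 circular shifts of bins within chromosomes.

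Samples, tests, the alternatives named for them and the rule for named regions were fixed before the data were examined. That rule takes, per contrast and direction, the 5 longest runs of adjacent called bins with up to 1 uncalled bin bridged, and the 8 bins with the largest change whose replicates do not overlap between the states, at least 2 Mb apart. The rule asked for genes in those regions. The gene table used carries coordinates of another assembly than hg19, so regions are named by position and class, and gene lists were not analysed here. The alternatives were quantile normalization, unit SD and median centring of the profiles, a pseudocount of 0.5, no trend, a replicate block, a minimum change of 0.5 (treat), means of 5 adjacent bins, autosomes alone, removal of the tenth of bins lowest in Dam-only, each replicate left out in turn, other thresholds for domains, and windows of 1 and 5 Mb at chromosome ends. Further alternatives were chosen after seeing the data: removal of bins at the chromosome maximum, weights from the recovered reads, and several of the settings above for results they had not been planned for. Profiles by distance from chromosome ends, flanks of the largest gap and domain size were also chosen after seeing the data.

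The test was checked on simulated reads for 26120 bins of the OIS and cycling contrast. With 30% of bins changed, it recovered 29.2% of changes of 0.5 and 91.3% of changes of 1 on the log2 scale, and 3.63% of its calls were false. With 200 changed bins it recovered 0% and 37%, so a count of few calls says little about small changes. That draw also gave 6 false calls among unchanged bins, a larger share of its calls than in the first draw. Another 2 false calls arose in the quiescent contrast, where nothing had been changed. The simulated reads held counting noise alone, which the real replicates exceeded, so these rates are a best case. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The labels do not say what replicate numbers shared between states stand for. In the deposited column names, cycling and OIS libraries of the same number carry a common number that quiescent libraries lack. A further field of these names splits with state, since both OIS Dam-LaminB1 libraries carry ND there and both cycling ones another entry. Among Dam-only libraries that field sets OIS replicate 1 apart from the other OIS and cycling ones, and quiescent names lack it. The meaning of the common number and of the further field is not given in the sources used here.

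Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and the package data.table (version 1.17.8) were used.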

Results

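The study compared contact of the genome with the nuclear lamina in cycling, BRAF-senescent (OIS) and serum-starved quiescent Tig3 fibroblasts, by Dam-LaminB1 and Dam-only libraries with 2 replicates of each per state. Recovered depth was 2366288 to 3221243 reads per library. Values are log2(Dam-LaminB1 / Dam-only) in 27961 bins of 100 kb (hg19), given as mean ± SD of 2 replicates, and are relative to the rest of the same library. Bins fell into 9307 cLAD, 9415 fLAD, 6833 ciLAD and 847 fiLAD bins. In cycling cells the median log2 ratio was 0.46 ± 0.0014 (SD, n = 2) in constitutive domains (cLAD) and 0.24 ± 0.036 in facultative domains (fLAD), against −0.92 ± 0.027 in constitutive inter-domains (ciLAD) and −0.69 ± 0.063 in facultative inter-domains (fiLAD). Constitutive domains are known as gene-poor chromatin at the lamina in many cell types, and constitutive inter-domains as gene-rich chromatin of the nuclear interior.

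Across bins, which are not independent replicates, the replicates of a state correlated at r = 0.886 (rho 0.848) in cycling, 0.79 (rho 0.806) in OIS and 0.941 (rho 0.927) in quiescent cells. Cycling and quiescent profiles correlated at 0.807 to 0.837 (rho 0.79 to 0.816). OIS profiles correlated with cycling profiles at −0.0305 to 0.1 (rho −0.0442 to 0.0836) and with quiescent profiles at 0.214 to 0.303 (rho 0.21 to 0.294). These are all 15 pairs of profiles. The SD of the log2 ratio over bins was 0.67 ± 0.025 in cycling, 0.52 ± 0.077 in OIS and 1.03 ± 0.037 in quiescent cells.

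The comparison of OIS with cycling cells asks how lamina contact differs after oncogene-induced senescence. Constitutive domains had lower and constitutive inter-domains higher contact in OIS, to the point that the order of these classes was turned. In cLAD bins the median log2 ratio was −0.38 ± 0.11 (SD, n = 2) in OIS against 0.46 ± 0.0014 in cycling cells, a median change of −0.81 (0.572-fold), and 6662 of 9307 bins (71.6%) fell while 25 rose. In ciLAD bins it was 0.0078 ± 0.042 against −0.92 ± 0.027, a median change of 0.92 (1.90-fold), and 5110 of 6833 bins (74.8%) rose while 13 fell. With the pseudocount of 0.5 the cLAD and ciLAD changes were −0.53 and 0.56, and at unit SD −1.28 and 1.48. The fLAD bins had a median change of 0.04 (0.21 with quantile normalization, 0.28 at unit SD and 0.24 with median centring), with 1322 bins higher and 1493 lower, and the fiLAD bins one of 0.12, which quantile normalization turned to −0.01, with 122 higher and 42 lower.

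**Figure D1:**
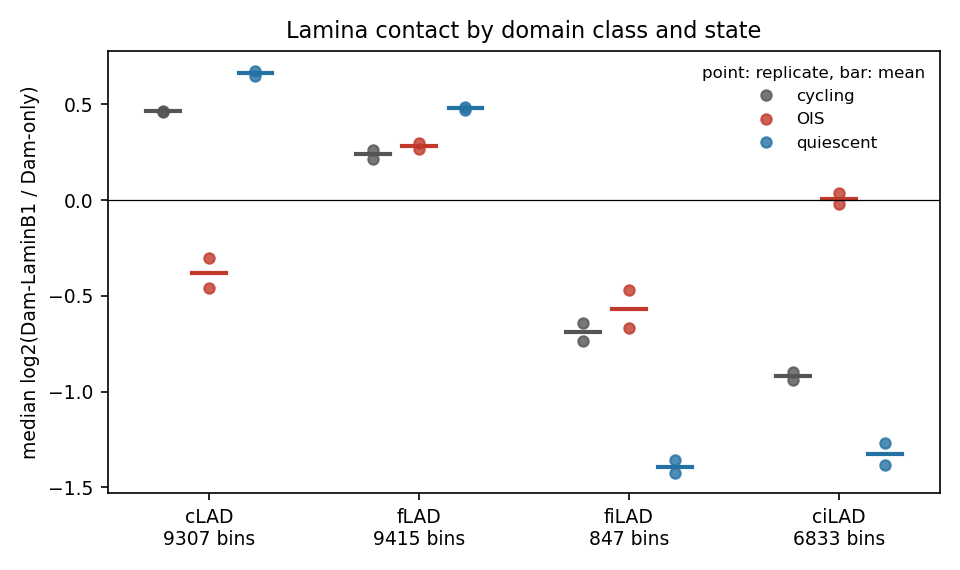
Median log2(Dam-LaminB1 / Dam-only) per domain class (y axis) in the classes cLAD, fLAD, fiLAD and ciLAD (x axis), with a point per replicate and a bar for the mean of 2 replicates of cycling, OIS and quiescent cells. OIS lies at −0.38 in cLAD and 0.0078 in ciLAD bins against 0.46 and −0.92 in cycling cells, whereas quiescent cells lie at 0.66 and −1.33, an order against cycling cells that turns in both classes when profiles are scaled to unit SD or quantile normalized.

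The authors' domain calls placed 62.3% of 55655 bins of 50 kb (1734.95 Mb) inside domains in cycling cells and 46.1% (1284.15 Mb) in OIS. Of 34699 bins inside domains in cycling cells, 15337 (44.2%) were inside in OIS, below the 16012 that independent placement of the calls would give, and 19362 (968.1 Mb) were not. With domains of both states taken as 100 kb bins with a log2 ratio above 0.5 in both replicates, 8.77% were kept. That share is close to, and not below, the OIS coverage at this threshold, which independent placement would give. Another 10346 bins (517.3 Mb) were inside in OIS alone of the pair. Of the bins lost, 74.6% were cLAD, and 79.9% of the cycling domain bins of that class (14435 of 18056) were lost. Of the bins gained, 75.6% were ciLAD, and 55.6% of that class outside domains in cycling cells was gained. Facultative domains kept 70.4% of their cycling domain bins, and 59.1% of that class outside domains in cycling cells was gained. Of all bins of a class, 68.3% of fLAD, 19.3% of cLAD and 56.0% of ciLAD bins were inside in OIS. The shares kept in fLAD and cLAD (20.1%) and gained in ciLAD thus lay near those of independent placement within the class. Domain lengths had a median of 1 Mb in both states, with 942 domains in cycling cells and 568 in OIS, and the longest run in OIS covered 26.85 Mb on chromosome 12 from 100700001 to 127550000.

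Large blocks changed together. On chromosome 9 from 125600001 to 141100000 (15.5 Mb, 90.3% ciLAD), 149 of 154 bins rose and the mean went from −1.02 ± 0.0080 (SD, n = 2) in cycling cells to 0.21 ± 0.11 in OIS. The end of chromosome 22 from 35600001 to 51200000 (15.6 Mb) went from −0.98 ± 0.0060 to 0.20 ± 0.10, and chromosome 11 from 67700001 to 79000000 (11.3 Mb) from −1.02 ± 0.012 to 0.25 ± 0.089. The next longest runs that rose lay on chromosome 6 from 29600001 to 38400000 (change 1.20) and on chromosome 4 from 400001 to 8900000 (change 1.36). Among runs that fell, chromosome 13 from 80900001 to 94500000 (13.6 Mb, 83.7% cLAD) went from 0.32 ± 0.014 to −0.85 ± 0.14, and from 61100001 to 74300000 (13.2 Mb, 93.2% cLAD) from 0.29 ± 0.011 to −0.91 ± 0.15. Chromosome 5 from 20900001 to 30900000, which is 100% cLAD, went from 0.46 ± 0.0020 to −0.72 ± 0.13, and runs on chromosome 3 from 75900001 to 86900000 and chromosome 4 from 58600001 to 69900000 changed by −1.11 and −1.02. The single bins with the largest changes were a ciLAD bin on chromosome 13 from 114300001 to 114400000 (2.77, SE 0.38, limma adjusted p = 0.000109; cycling replicates at −3.08 and −1.77) and a cLAD bin on chromosome 5 from 29600001 to 29700000 (−2.55, SE 0.24, limma adjusted p = 7.81e-05). The first rests on few reads, with 18.4 expected against a median of 99.5 per bin in 1 library.

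**Figure D2:**
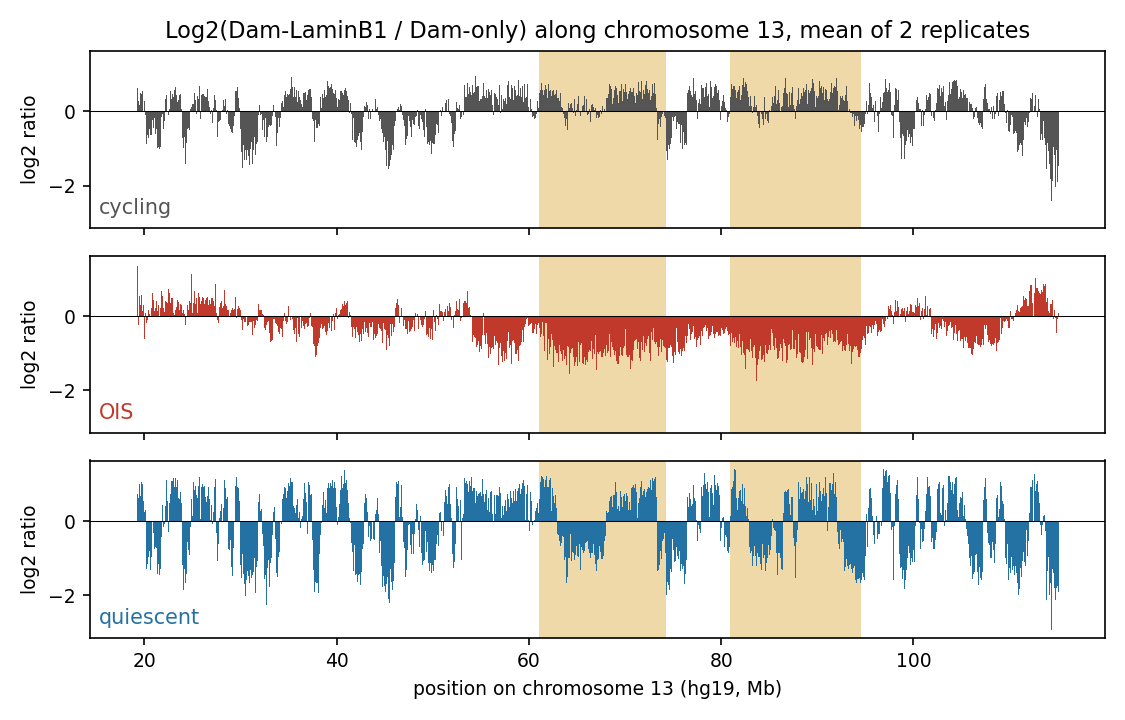
Log2(Dam-LaminB1 / Dam-only) in bins of 100 kb (y axis, bars are the mean of 2 replicates) along chromosome 13 (x axis, hg19, Mb) in cycling, OIS and quiescent cells, with the shaded blocks marking the runs from 61100001 to 74300000 and from 80900001 to 94500000. In these runs cycling cells average 0.29 and 0.32 and OIS cells −0.91 and −0.85.

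Over all bins, 6929 (24.8%, 692.9 Mb) rose in OIS with a median change of 0.97 and 8539 (30.5%, 853.9 Mb) fell with a median change of −0.92 (limma, n = 2 per state, adjusted p under 0.05). The remaining 12493 bins did not pass. Centring each profile at its median moved the median change of all bins from −0.06 to 0.15 and the share of higher bins among calls from 44.8% to 59.7% (9085 higher, 6136 lower). A test for changes over 0.5 called 2494 higher and 2516 lower.

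Chromosome means changed with the same sign in every scaling for 14 of 23 chromosomes, which include those named here. Chromosome 22 (72.0% ciLAD) rose by 1.02 (SE 0.0495, limma adjusted p = 9.24e-30), chromosome 19 (68.5% ciLAD) by 0.74 (SE 0.0514) and chromosome 17 (58.4% ciLAD) by 0.61 (SE 0.0516). Chromosome 4 (53.4% cLAD) fell by 0.47 (SE 0.0321, limma adjusted p = 9.83e-22) and chromosome 13 (44.3% cLAD) by 0.43 (SE 0.0338). The SE pool the spread over chromosomes, so these p-values are too small. On chromosome 4 the SD of the replicates was 0.0862 in OIS and 3e-04 in cycling cells. In the order 22, 19, 17, 4 and 13 the changes were 0.60, 0.37, 0.34, −0.31 and −0.27 with the pseudocount of 0.5 and 1.73, 1.24, 1.03, −0.75 and −0.71 at unit SD, and median centring gave −0.26 and −0.22 for chromosomes 4 and 13. In all, 10 chromosomes rose and 11 fell. Without cycling replicate 2 only 6 rose, and 4 fell once each profile was centred at its median.

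**Figure D3:**
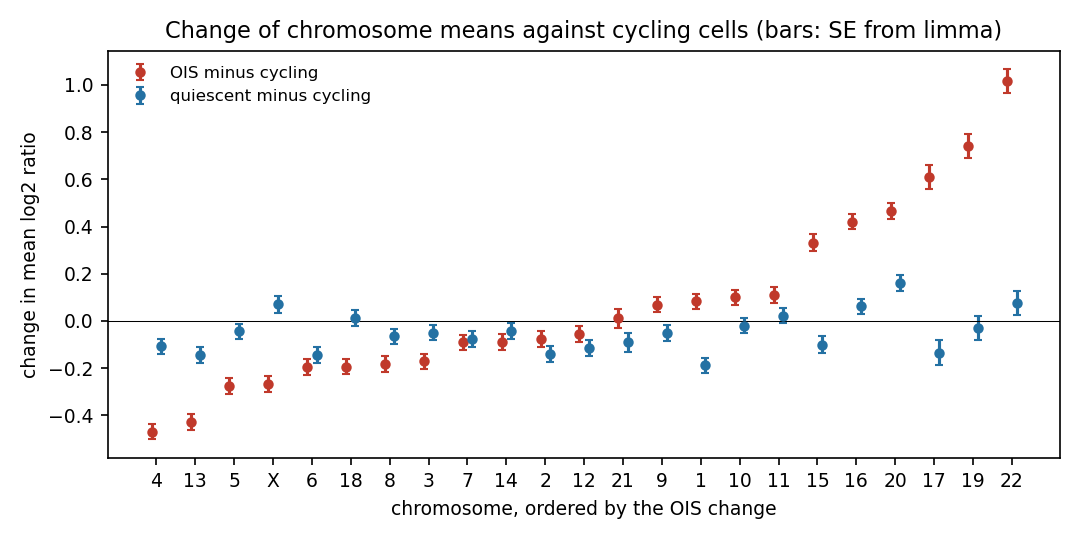
Change in the mean log2 ratio per chromosome (y axis) against cycling cells for OIS and quiescent cells, with chromosomes ordered by the OIS change (x axis), points for the estimate from 2 replicates per state and bars for the SE from limma, which pools the spread over chromosomes. OIS changes run from −0.47 on chromosome 4 to 1.02 on chromosome 22, and quiescent changes from −0.19 on chromosome 1 to 0.16 on chromosome 20.

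Chromosome ends had higher contact in OIS. In 773 bins within 2 Mb of an outer end the mean log2 ratio was −0.57 ± 0.0059 (SD, n = 2) in cycling cells, 0.27 ± 0.11 in OIS and −0.61 ± 0.068 in quiescent cells. With all chromosomes pooled, end bins lay below the other bins in cycling cells (difference −0.54 ± 0.0092) and above them in OIS (0.35 ± 0.14), a change of 0.90. Differences between chromosomes therefore enter these values. Class composition enters them as well, with 928 ciLAD, 755 fLAD, 205 cLAD and 11 fiLAD bins within 5 Mb of an end. Mean changes from cycling to OIS within 5 Mb and over 50 Mb away were 1.25 and 0.73 in ciLAD and −0.40 and −0.87 in cLAD bins. In fLAD bins they were 0.35 and −0.21, and in fiLAD bins 0.70 and −0.02. Of the 773 bins, 494 rose and 32 fell. No circular shift gave a change as large (p = 0.001, the smallest that 1000 shifts can give), while the exact permutation test of the 2 against 2 replicates gave p = 0.3333, the smallest it allows. Contact in OIS was 0.35 ± 0.077 at 2 to 5 Mb from an end and −0.25 ± 0.074 over 50 Mb away, where cycling cells had −0.27 ± 0.019 and 0.08 ± 0.0020.

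**Figure D4:**
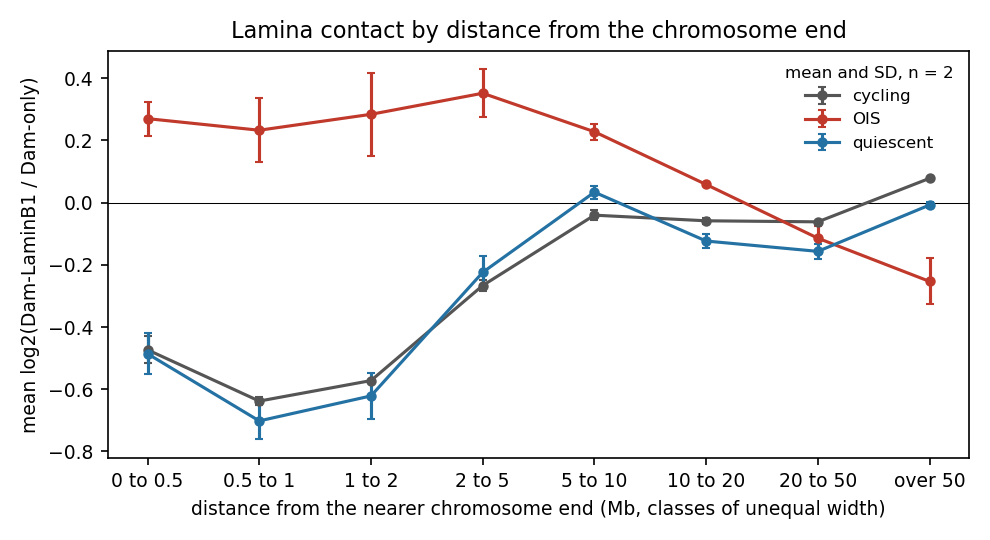
Mean log2(Dam-LaminB1 / Dam-only) (y axis) by distance from the nearer chromosome end in classes of unequal width (x axis, Mb), with points for the mean and bars for the SD of 2 replicates of cycling, OIS and quiescent cells. OIS goes from 0.27 in the outermost 0.5 Mb to −0.25 over 50 Mb away, while cycling cells go from −0.47 to 0.08 and quiescent cells from −0.49 to −0.0075.

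The comparison of quiescent with cycling cells asks how lamina contact differs in growth arrest without the oncogene. Domains of cycling cells were mostly kept. The authors' calls placed 51.9% of bins (1445.05 Mb) inside domains, and 27397 of the 34699 cycling domain bins (79.0%) were inside in quiescent cells, above the 18019 of independent placement. The lower coverage than in cycling cells turned for a log2 ratio above 0.5 in both replicates (33.6% against 13.3%). Quiescent cells lost 20.6% of the cycling domain bins of cLAD and 20.7% of those of fLAD, and gained 4.04% of the ciLAD bins that lay outside. Their domains were more numerous (1407) and shorter, with a median length of 0.65 Mb. A total of 7302 bins (365.1 Mb) were lost and 1504 (75.2 Mb) gained.

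The 5 longest runs with lower contact in quiescent cells covered 4.8 to 15.9 Mb, mostly in constitutive domains. The longest, on chromosome 1 from 183700001 to 199600000 (15.9 Mb, 66.7% cLAD), went from 0.12 ± 0.023 (SD, n = 2) in cycling to −0.97 ± 0.032 in quiescent cells, with −0.82 ± 0.16 in OIS. Runs on chromosome 12 from 86100001 to 94300000 (8.2 Mb), chromosome 4 from 134200001 to 141300000 (7.1 Mb) and chromosome 2 from 192400001 to 198400000 (6 Mb) changed by −1.09, −1.09 and −0.91. On chromosome 4 from 124000001 to 128800000 (4.8 Mb, 81.3% cLAD) the mean went from −0.14 ± 0.057 to −1.48 ± 0.13. The 5 longest runs with higher contact covered 1.4 to 2.2 Mb. Chromosome 22 from 48100001 to 50200000 (2.1 Mb) went from −0.12 ± 0.11 to 0.80 ± 0.11, chromosome 3 from 125600001 to 127300000 (82.4% fLAD) from −0.34 ± 0.034 to 0.57 ± 0.045, and chromosome 5 from 500001 to 1900000 (85.7% ciLAD) from −0.65 ± 0.17 to 0.22 ± 0.23. Runs on chromosome 16 from 5500001 to 7700000 and chromosome 20 from 58900001 to 60500000, 100% and 93.8% fLAD, changed by 0.66 and 0.85. All 10 runs kept their direction when profiles were scaled to unit SD or quantile normalized. They were chosen by their calls before scaling, which favours a kept direction. Over all bins limma called only 56 higher and 70 lower at unit SD. With quantile normalization it called 0 (2347 higher and 2188 lower at an unadjusted p under 0.05). The run on chromosome 1 alone held 148 called bins, so most of its calls were lost in both settings.

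By class, the median change was 0.13 in cLAD, 0.21 in fLAD, −0.39 in ciLAD and −0.68 in fiLAD bins, of which the cLAD and ciLAD changes turned to −0.11 and 0.18 at unit SD and to −0.13 and 0.11 with quantile normalization. In the same settings the fLAD change was 0.09 and 0.06 and the fiLAD change −0.23 and −0.15. In cLAD bins 744 rose and 1537 fell, and in fLAD bins 1631 rose and 998 fell. In ciLAD bins 374 rose and 1711 fell. Of 847 fiLAD bins, 454 (53.6%) fell and 3 rose. Chromosome ends changed by 0.02 against the rest (97 bins higher, 110 lower, circular shift p = 0.722, exact permutation p = 1), and by 0.31 at unit SD, where no shift gave as much (p = 0.001, the smallest possible). Chromosome 20 rose by 0.16 (SE pooled over chromosomes 0.0331, limma adjusted p = 8.54e-05), and 9 chromosomes fell, chromosome 1 by 0.19 (pooled SE 0.0329, limma adjusted p = 5.56e-06). At unit SD 9 rose and 8 fell, and with quantile normalization 9 rose and 6 fell. Without cycling replicate 1 or cycling replicate 2 only 1 chromosome fell, without the latter 0 rose (limma, 1 at an unadjusted p under 0.05), and without quiescent replicate 1 4 fell, whereas without OIS replicate 1 or OIS replicate 2 15 fell and 3 rose.

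In total, 2882 bins (10.3%, 288.2 Mb) rose in quiescent cells with a median change of 0.73 and 4980 (17.8%, 498 Mb) fell with a median change of −0.87 (limma, n = 2 per state). At unit SD 56 bins rose and 70 fell, with quantile normalization limma called 0 (2347 higher and 2188 lower at an unadjusted p under 0.05), and a test for changes over 0.5 called 27 and 200. Leaving out cycling replicate 1, cycling replicate 2, quiescent replicate 1 or quiescent replicate 2 left 1144, 732, 1083 and 1308 bins higher and 2317, 1743, 2716 and 3555 lower.

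The direct comparison of OIS with quiescent cells tests whether the arrested states differ from each other. In ciLAD bins 5978 of 6833 (87.5%) were higher in OIS and 18 lower, and in cLAD bins 6405 of 9307 (68.8%) were lower and 466 higher. Of fiLAD bins 597 were higher in OIS and 2 lower, and of fLAD bins 1366 were higher and 2422 lower. The longest run with higher contact in OIS lay on chromosome 9 from 125600001 to 135300000 (9.7 Mb), with 0.11 ± 0.093 (SD, n = 2) in OIS and −1.47 ± 0.12 in quiescent cells. Others lay on chromosome 11 from 71500001 to 79200000 (change 1.56), on chromosome 1 from 22700001 to 29600000 (1.60) and on chromosome 19 from 300001 to 6500000 (1.51) and from 43900001 to 50600000 (1.38), the last pair being 100% ciLAD. The longest run with lower contact lay on chromosome 5 from 21800001 to 30900000 (100% cLAD), with −0.74 ± 0.12 in OIS and 0.59 ± 0.013 in quiescent cells, followed by chromosome 6 from 91300001 to 99800000 (−1.33), chromosome 4 from 58000001 to 66300000 (−1.34), chromosome 8 from 108800001 to 116300000 (−1.32) and chromosome 13 from 53300001 to 59900000 (−1.33).

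Over all bins, 8889 (31.8%) were higher in OIS than in quiescent cells with a median change of 1.16 and 9227 (33.0%) were lower with a median change of −1.02 (limma, n = 2 per state). Chromosome ends lay 0.87 higher against the rest in OIS than in quiescent cells (472 bins higher, 78 lower, circular shift p = 0.001, the smallest possible, exact permutation p = 0.3333). Centring each profile at its median gave 10306 higher and 7496 lower. Unit SD gave 7214 higher and 7207 lower, and quantile normalization 6841 and 6452. Which direction has more bins, and how many bins are called, therefore depends on the scaling. A test for changes over 0.5 called 5253 bins higher and 4693 lower.

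The Dam-only libraries, which mark accessible DNA, were compared in the same way as a background. Their 15 pairs correlated at r = 0.917 to 0.949 across bins (rho 0.89 to 0.94). Between OIS and cycling cells limma called 0 bins, with 1232 higher and 1180 lower at an unadjusted p under 0.05, and between quiescent and cycling cells 0, with 1512 higher and 1954 lower. Between OIS and quiescent cells 2 bins were higher and 2 lower. Means of 5 adjacent bins, with less counting error, called 0.684%, 2.91% and 11.7% of 5698 regions for these contrasts.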

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

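The tests at unit SD of chromosome means, of means of 5 adjacent bins and of bins with opposite changes, and those without bins at the chromosome maximum, of exchanged libraries, of lost contrast and within classes by distance were chosen only after the result was seen.

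Several results moved one way in OIS and the other way in quiescent cells. In cLAD bins every replicate median was below cycling cells in OIS and above them in quiescent cells, with a median change between OIS and quiescent cells of −0.91. In ciLAD bins OIS lay above and quiescent cells below, with a change of 1.25. These class differences were not tested across bins, and at unit SD the quiescent changes turn (−0.11 and 0.18), so that OIS and quiescent cells then move the same way in both classes. Chromosomes 1, 15 and 17 rose in OIS and fell in quiescent cells, and the direct limma test gave differences of 0.27 (SE 0.0329, adjusted p = 1.66e-11), 0.43 (SE 0.0363, adjusted p = 1.4e-17) and 0.74 (SE 0.0516, adjusted p = 1.3e-21). These p-values pool the spread over chromosomes of the same profiles and are too small. On chromosomes 15 and 17 the quiescent change turned at unit SD (0.09 and 0.20). Without cycling replicate 1, or without cycling replicate 2, only 1 of 23 chromosomes fell in quiescent cells. A total of 457 bins (45.7 Mb; 384 cLAD, 58 fLAD) fell in OIS, rose in quiescent cells and differed between them in limma, but at unit SD limma called the quiescent rise in only 1 of them (50 at an unadjusted p under 0.05) and with quantile normalization in 0 (51), while all 457 kept the sign they were selected for at unit SD. Another 1222 bins (122.2 Mb; 1028 ciLAD, 114 fLAD, 42 fiLAD) rose in OIS, fell in quiescent cells and differed between them, and limma called the quiescent fall in 0 of them at unit SD (128 at an unadjusted p under 0.05) and in 0 with quantile normalization (114), while 1106 kept the sign they were selected for at unit SD.

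The pattern weighed first is that the OIS profile was unlike the cycling profile, with constitutive domains below and constitutive inter-domains above it. Exchanged Dam-LaminB1 and Dam-only libraries are argued against, since the lowest correlation of an OIS Dam-only library with Dam-only libraries of other states (0.917) exceeds the highest of an OIS Dam-LaminB1 library with them (0.791). A change of the Dam-only denominator is argued against, since 99.96% of called bins (95.9% as calls) moved the same way in the Dam-LaminB1 libraries alone. Loss of contrast alone is argued against, since it cannot put cLAD below ciLAD bins, as found in both OIS replicates (nearest to 0, −0.28; mean −0.39 ± 0.15 SD, n = 2). A rearrangement of lamina contact in senescence stays open as a hypothesis, as do culture differences that the labels do not record and GC content, which were not tested. The further field of the column names separates OIS from cycling Dam-LaminB1 libraries. A handling difference behind that field, if there is one, cannot be told apart from the state.

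The next pattern is the many bins called between quiescent and cycling cells. Whether a wider range of the quiescent profiles is the only cause cannot be decided here. Single bins gave 56 higher and 70 lower at unit SD against 2882 and 4980 as deposited. With quantile normalization limma called 0 (2347 higher and 2188 lower at an unadjusted p under 0.05). Of 5698 means of 5 adjacent bins, 21.2% passed at unit SD (550 higher, 655 lower), against 1569 higher and 1751 lower as deposited. Bins were scaled before averaging, so these means were not themselves at unit SD and the range may still differ between states. Without bins held at the chromosome maximum, 27.7% of bins were called. The bins removed are 6.57% of those tested, far fewer than the 7862 called, so their removal could not undo most calls. This test shows only that most calls lie elsewhere and cannot decide on an effect of the maximum. Unequal depth is argued against as the source of that range, since with all libraries thinned to 2146740 reads the SD of the quiescent profiles was still 1.45 to 1.59 times that of the cycling profiles. The wider range may come from the quiescent state or from a difference in library preparation, which the design does not separate.

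The last pattern is the fall of the OIS level with distance from the chromosome end. A mix of classes is argued against, since OIS bins within 5 Mb of an end exceeded those over 50 Mb away by 0.32 (SD 0.13, n = 2) in ciLAD, 0.54 (SD 0.086) in cLAD and 0.56 (SD 0.12) in fLAD bins. The Dam-only level of bins near ends is argued against, since 97.1% of the difference within classes between bins within 10 Mb and over 50 Mb of an end remained when bins were also matched on that level (0.43 before, 0.41 after). Both comparisons pool chromosomes, and only long chromosomes hold bins over 50 Mb from an end. Differences between short and long chromosomes therefore enter both. For higher OIS levels of short chromosomes, 18 of 23 chromosomes had a negative rank correlation with distance in both OIS replicates, against 6 in cycling and 8 in quiescent cells. That count lies between the bounds of 15 and 19 set beforehand, so the rule gave no verdict. A difference in level between chromosomes cannot produce a correlation within one, so these values show a fall within most chromosomes. How much of the pooled fall comes from short chromosomes was not separated. The median within chromosomes was −0.29 and −0.26 in the OIS replicates, with chromosomes 9, 16, 19, 20 and 22 running the other way, and GC content and gene density were not tested.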

How the results depend on the processing

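Tests chosen only after the result was seen were removal of bins at the chromosome maximum, weights from recovered reads, every alternative for the Dam-only libraries and chromosome means, quantile, median and pseudocount settings for classes, quantile and pseudocount settings for ends, and the domain threshold of 0 in both replicates. Counted over results and settings, 244 values kept their direction and side of the threshold or moved by less than the replicate spread. Another 40 moved by more, 33 gained and 30 lost calls by over 1.5 times or crossed the threshold, and 6 changed sign. For the 30 named runs under the scalings, the pseudocount and each replicate left out, 143 values moved by less than the replicate SD, 97 by more, and none changed sign. These runs were chosen by their calls in the main setting, which favours a kept sign. The shares of bins called between OIS and cycling cells stayed within 1.5 times of the reported ones under all alternatives except the test for a minimum change. Counting error (median 0.21 per log2 ratio) limits single bins, and where a replicate is left out its lone partner is assumed to vary like the other states. Alternatives meant for count tables and for gene lists were not run. Except where stated, the cause of a difference was not tested.

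Of quiescent against cycling bins, 0% were called higher and 0% lower with quantile normalization (limma, 2347 and 2188 bins at an unadjusted p under 0.05), 0.200% and 0.250% at unit SD, 0.0966% and 0.715% with the minimum change of 0.5, 27.5% and 30.7% of means of 5 adjacent bins, and 2.62% to 10.9% and 6.23% to 17.6% with a replicate left out. The minimum change, a stricter test by construction, gave 8.92% higher and 9.00% lower for OIS against cycling and 18.8% and 16.8% for OIS against quiescent.

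The replicate numbers are shared between states, but deviations of same-numbered replicates from their state means correlated at 0.036 (cycling and OIS), 0.001 (cycling and quiescent) and −0.057 (OIS and quiescent) across bins. This gives no sign of pairing by number and does not exclude that same-numbered samples share a culture or a day. With the replicate block, 6869 bins rose and 8457 fell in OIS, 2814 and 4918 in quiescent cells against cycling, and 8856 and 9224 between OIS and quiescent cells. In Dam-only libraries the block called 0.0286% between OIS and quiescent cells, and it moved no other count by over 1.5 times.

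Dam-only bins called between OIS and cycling were 0.00358% at unit SD and with median centring, 0.684% of means of 5 adjacent bins, 0.00383% without bins at the maximum and 0% to 0.00358% with a replicate left out. Between quiescent and cycling they were 0.0179% with median centring, 2.91%, 0.0498% and 0% to 0.00715% in the same order. Between OIS and quiescent they were 0.0501% with quantile normalization, 0.0680% at unit SD, 0.283% with median centring, 0% without trend (limma, 2364 higher and 1277 lower at an unadjusted p under 0.05) and with the minimum change (22 and 2), 11.7% of means of 5 adjacent bins, 0.0264% on autosomes, 0.0318% without the bins lowest in Dam-only, 0.364% without bins at the maximum and 0% to 0.0107% with a replicate left out.

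Chromosomes called lower in OIS than cycling were 17.4% with median centring, and those called higher 26.1% to 43.5% with a replicate left out. For quiescent against cycling, 39.1% were higher with quantile normalization and at unit SD, 21.7% with median centring, 8.70% without trend, 13.04% with the pseudocount of 0.5 and 0% to 13.04% with a replicate left out (limma, 1 chromosome at an unadjusted p under 0.05 in the setting with 0), and 4.35% to 65.2% were lower with a replicate left out. For OIS against quiescent, 47.8% were lower with quantile normalization and 78.3% higher with median centring.

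For OIS minus cycling the class medians changed as follows. The cLAD median was −0.94 with quantile normalization, −1.28 at unit SD, −0.60 with median centring and −0.53 with the pseudocount of 0.5. In the same order ciLAD gave 1.13, 1.48, 1.13 and 0.56. The fLAD median was 0.21, 0.28 and 0.24 with the scalings, and the fiLAD median −0.012 with quantile normalization, a change of sign, and 0.32 with median centring. For quiescent minus cycling, cLAD turned to −0.13 with quantile normalization and −0.11 at unit SD and was 0.16 with median centring, 0.092 with the pseudocount and 0.10 to 0.13 with a replicate left out. The fLAD median was 0.062, 0.088 and 0.14 with quantile normalization, unit SD and the pseudocount, and 0.17 to 0.22 with a replicate left out. The ciLAD median turned to 0.11 and 0.18 and was −0.20 with the pseudocount, and the fiLAD median was −0.15, −0.23 and −0.42. Chromosome ends against the rest, quiescent minus cycling, gave 0.31 at unit SD, 0.18 with quantile normalization and −0.0098 to 0.058 with a replicate left out, the lowest, a change of sign, without quiescent replicate 2.

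Domain coverage was 51.2% in cycling, 36.8% in OIS and 49.4% in quiescent cells for a log2 ratio above 0 in both replicates, 13.3%, 8.69% and 33.6% for one above 0.5, and 57.3%, 44.6% and 52.6% for a mean above 0. Cycling domain bins kept in OIS were 36.5%, 8.77% and, at the same quantile of each profile, which fixes coverage by construction, 48.8%. For a ratio above 0 and above 0.5 these shares lie near the OIS coverage (36.8% and 8.69%), which independent placement would give. In quiescent cells 83.4%, 83.1%, 83.8% and 86.3% were kept for a ratio above 0, above 0.5, a mean above 0 and the same quantile.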

Other observations

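The summaries by domain size, by distance within classes and at the flanks of the largest gap were chosen only after the result was seen. Larger cycling domains lost a larger share of their bins in OIS. Domains up to 0.5 Mb lost a mean of 25.2% (311 domains), those of 0.5 to 1 Mb 30.5%, those of 1 to 2 Mb 32.6% (174), those of 2 to 5 Mb 50.9% (203) and those over 5 Mb 72.8% (SD 33.6 over 87 domains). The mean share of cLAD bins went from 18.8% in the smallest to 70.4% in the largest of these classes, so size and class move together and were not separated. In quiescent cells the mean share lost lay between 18.1% and 23.6% in the same size classes. The longest cycling domain, on chromosome 5 from 17600001 to 32050000, covered 14.45 Mb, and the longest quiescent domain, on chromosome 2 from 75900001 to 84850000, covered 8.95 Mb.

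Within classes, with chromosomes pooled, OIS contact fell with distance from the chromosome end, and quiescent contact did so to a smaller extent in domains. Cycling contact was lower near ends in ciLAD bins. In fLAD bins the OIS level was 0.56 ± 0.082 (SD, n = 2) within 5 Mb of an end and 0.0032 ± 0.039 over 50 Mb away, whereas cycling cells had 0.21 ± 0.038 and 0.21 ± 0.031 and quiescent cells 0.47 ± 0.021 and 0.26 ± 0.0039. In cLAD bins OIS had 0.09 ± 0.032 and −0.46 ± 0.12, quiescent cells 0.70 ± 0.0016 and 0.37 ± 0.017, and cycling cells 0.48 ± 0.042 and 0.41 ± 0.00011. In ciLAD bins OIS had 0.17 ± 0.12 and −0.15 ± 0.011, quiescent cells −1.31 ± 0.099 and −1.21 ± 0.084, and cycling cells −1.08 ± 0.022 and −0.87 ± 0.032. Bins within 0.5 Mb of the largest gap of a chromosome (on 19 chromosomes) had 0.29 ± 0.022 in cycling, 0.26 ± 0.024 in OIS and 0.69 ± 0.0040 in quiescent cells, against −0.03 ± 0.0044, −0.08 ± 0.033 and −0.12 ± 0.023 over 10 Mb away. None of these values was tested.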
